A study of Homo sapiens with 45 samples.

How the data were processed

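Gene expression was measured by mRNA sequencing in 45 libraries of the human cell line HAP1, a near-haploid derivative of KBM-7, per the labels. The 6 genotypes were AAVS1 (the line used as reference here, named after a genomic site that is often edited as a neutral control), eS31 K113R, the single knockouts (KO) of ZNF598, GCN2 and RNF25, and a double knockout (DKO) labelled RNF25 GCN2 DKO. Cells of all 6 genotypes were left untreated or treated with 5 uM azacytidine (azaC), and AAVS1, RNF25 KO and GCN2 KO cells also with 25 nM halofuginone (HF), each for 4 h. Each of the 15 groups held 3 libraries, labelled only as biological replicates, with nothing further on how the cultures were separated. The p-values therefore measure the spread between these libraries. That spread includes a deviation that most pairs of libraries with the same replicate number shared, and the main fit did not remove it.

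RNA was isolated with a Maxwell RSC kit and polyA RNA libraries were made with the CORALL mRNA-Seq V2 kit, per the labels' protocols. The values deposited are raw counts per gene, aligned with STAR 2.7.10b and counted with HTSeq 0.9.1 on GRCh38, per the submitters' processing notes. The annotation release, the strand setting of the counting, and the use of molecular identifiers are not given in the sources used here. Whether reads of genes that overlap on opposite strands were told apart is therefore not stated. Protein-coding genes with 40 to 80% of exon length shared on the opposite strand only had a median total of 429 counts. That median was 104 with no exon shared, and 0 with over 80% shared on the same strand. Genes with opposite-strand overlap were thus not generally left without counts. The sets hold different genes and different extents of overlap, so these values cannot show or exclude a loss of part of the counts. They do not settle single genes with opposite-strand overlap either. Such overlap is given where found among the genes whose positions are printed, and was not looked up for the other named genes. For untreated eS31 K113R replicates 2 and 3, the title and genotype label read eS32_K223R, while the described column name reads eS31_K113R and the series design lists only eS31 K113R. These libraries were placed by the described column, and an alternative kept only replicate 1.

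All 45 columns were used, with 0 per-sample columns left out. The table held 60676 genes, of which 27878 had a count in some library, and 2862 of its entries, with 0.0286% of the counts, carried no symbol. Of the gene identifiers, 60357 matched a reference symbol table. Gene positions and exon overlaps were taken from a GRCh38 annotation. Total counts per library ran from 1135498 to 2478875 with a median of 1541554, and the median count of a tested gene in a library ran from 27 to 66 with a median of 38. No pair of libraries within a group was a copy of another, as the smallest chi-square per degree of freedom over 45 pairs was 3.01. Floors given for single genes cover counting error only, and the SE and SD include the spread between cultures.

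Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 11078, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood negative binomial model with a mean for each of the 15 groups, and 30 residual degrees of freedom, was fitted to all libraries, so that every comparison shared its estimate of spread. The common biological coefficient of variation was 22.1%. The 26 comparisons were each drug against untreated within a genotype, each untreated genotype against AAVS1, differences between genotypes in a drug response, and azaC against HF within AAVS1 and RNF25 KO. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within a comparison, and a gene passed at an adjusted p under 0.05. Standard errors (SE) come from the fold change and the F statistic. Levels are CPM, the counts divided by the library total and rescaled, on TMM-scaled library sizes, with the SD over 3 libraries, and per-library log2 CPM used a prior count of 2.

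Fixed before the data were examined were the groups, the comparisons, the alternative analyses, the rule for named genes and 23 gene lists with 520 entries. The lists covered the integrated stress response, cytosolic aminoacyl-tRNA synthetases, amino acid synthesis, amino acid transporters, ER chaperones and ERAD, p53 targets, immediate early genes, cholesterol synthesis, NRF2 targets, interferon-stimulated genes, methylation-silenced germline genes, S phase, G2/M, cytosolic ribosomal proteins, ribosome biogenesis, ribosome collision and quality control, autophagy, pyrimidine and nucleoside metabolism, heat shock, mitochondrial encoded mRNAs, and haematopoietic, epithelial and neural cell markers. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated for each list. Of 122 list tests that passed with the preset correlation, 54 also passed with an estimated correlation: 14 of 16 for the integrated stress response, 13 of 13 for transporters, 8 of 12 for synthesis, 7 of 14 for heat shock, 5 of 11 for tRNA synthetases, 4 of 9 for immediate early genes and 3 of 6 for cholesterol synthesis. None of the passes of the NRF2, p53, mitochondrial, ribosomal protein, ribosome biogenesis, S phase, G2/M and ER lists held.

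The genes named are the edited genes, and then, among those that passed with a symbol, a mean of at least 1 CPM and library values that did not overlap between the groups compared, the 10 with the largest change in each direction for azaC in AAVS1, azaC in RNF25 KO, HF in AAVS1 and the difference between RNF25 KO and AAVS1 in the azaC response, and the 5 largest elsewhere. Of each list described, the 4 members with the smallest adjusted p are named, and ATF3, DDIT3, ASNS, CHAC1, TRIB3, SESN2 and PPP1R15A are given whatever their values. Where no count was seen in a group, a fold is a lower bound against 3 counts over that group.

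Alternative analyses fixed beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, the replicate number as a block, a fit to only the libraries of the groups compared, each library left out in turn, and the single eS31 K113R untreated library with that title. Added after the data were examined were offsets corrected for transcript GC content, and a fit without AAVS1 untreated replicate 2 and RNF25 KO azaC replicate 2, the libraries with the lowest and the highest GC slope. The procedure was tested in 20 simulations of counts drawn from the real means and library sizes, where it tested 10662 to 10728 genes. For azaC in RNF25 KO it recovered 39.2% of 1303 genes changed 2-fold, 82.8% of 1314 changed 4-fold and 94.7% of 1291 changed 8-fold. For the difference between RNF25 KO and AAVS1 it recovered 15.2%, 64.9% and 85.4%. Unchanged genes made up 4.18% and 5.53% of the calls in these comparisons, and a comparison with no change called 3 genes over the 20 simulations. The simulated spread between libraries depended on expression level alone. It held no spread particular to a gene, no deviation shared by replicate number and no slope on GC content. These shares may therefore not hold for the real libraries. One gene that the rule for named genes would name is not reported here. Figures were drawn with Python 3.11.15.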

Results

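HAP1 cells of 6 genotypes were profiled by polyA mRNA sequencing, untreated or 4 h after 5 uM azacytidine (azaC), a cytidine analogue that is incorporated into RNA and DNA, or 25 nM halofuginone (HF), an inhibitor of prolyl-tRNA synthetase that activates the kinase GCN2. RNF25 and ZNF598 are ubiquitin ligases that act at stalled ribosomes, GCN2 (gene EIF2AK4) is a kinase of the integrated stress response, the RNF25 GCN2 DKO line is labelled as lacking both RNF25 and GCN2, and eS31 K113R carries a lysine substitution in the ribosomal protein made from RPS27A. The series title places the work on RNF25, azaC-induced mRNA damage and the integrated stress response, so the comparisons ask how each genotype changes the response to azaC, with HF as a known activator of GCN2. Each of the 15 groups held 3 libraries, with 1135498 to 2478875 counts per library, and 11078 genes were tested. Several libraries stood apart. RNF25 KO azaC replicate 2 had the highest total, the smallest mitochondrial share (3.14%, against a median of 7.08%) and the highest slope on transcript GC content (0.339, against a median of 0.0154 and a next highest of 0.138). AAVS1 untreated replicate 2 had the lowest slope (−0.491, next lowest −0.189). Changes are log2 fold changes ± SE from edgeR with n = 3 libraries per group, and p-values are Benjamini-Hochberg adjusted. Unless exceptions are given beside them, named genes stayed past the threshold when any 1 library of the comparison was left out. This was not examined for HERPUD1, XBP1, HSPA5, MANF, MAP2 and ME1, for GADD45A with azaC in RNF25 KO, for NQO1 and CGAS outside eS31 K113R, or for the genes higher in all 5 untreated lines.

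The edited genes were examined in every group. EIF2AK4 (ENSG00000128829, chromosome 15, 39934146 to 40035591, GRCh38) stood at 43.96 ± 1.64 CPM (SD, n = 3) in untreated AAVS1 and at 21.95 ± 2.41 CPM in untreated GCN2 KO, with 22.3 ± 5.39 and 15.9 ± 1.52 CPM in GCN2 KO after azaC and HF. In the libraries labelled RNF25 GCN2 DKO it stood at 39.6 ± 3.73 CPM untreated and 35.2 ± 12.7 CPM after azaC, so its mRNA was not lowered there to the level of GCN2 KO, and the label of that line has no check from this transcript. ZNF598 (ENSG00000167962, chromosome 16, 1997654 to 2009823) stood at 37.2 ± 5.97 CPM in untreated ZNF598 KO and 62.6 ± 10.7 CPM in untreated AAVS1, and at 45.6 ± 2.52 and 89.8 ± 3.26 CPM after azaC. RNF25 (ENSG00000163481, chromosome 2, 218663864 to 218672411) had 0 to 7 counts in any library and 91 counts in all, too few to test, so it checks nothing. The exons of ZNF598, RNF25 and RPS27A lie in part under exons of the opposite strand (10.7%, 11.2% and 5.65% of their length). RPS27A (ENSG00000143947, chromosome 2, 55231903 to 55235853) had 7174 to 16517 counts per library, and a point mutation does not show in its count.

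In AAVS1, azaC raised genes of the integrated stress response, the program that cells start when translation initiation is limited by phosphorylated eIF2. CHAC1, a glutathione-degrading enzyme (ENSG00000128965, chromosome 15, 40952962 to 40956519), rose from 2.24 to 68.4 ± 5.83 CPM, a log2 change of 4.95 ± 0.61 (adjusted p = 1.48e-06). SESN2, an inhibitor of mTORC1 signalling (ENSG00000130766, chromosome 1, 28259527 to 28282491), rose from 56.9 ± 6.36 to 177.3 ± 21.03 CPM (1.64 ± 0.18, adjusted p = 1.0e-07). STC2, a secreted glycoprotein (ENSG00000113739, chromosome 5, 173314713 to 173329503), rose by 1.93 ± 0.25 (adjusted p = 2.44e-06) and DDIT4, another inhibitor of mTORC1 (ENSG00000168209, chromosome 10, 72273920 to 72276036), by 3.04 ± 0.39 (adjusted p = 2.68e-06). The transcription factors ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777), DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737) and CEBPB rose by 2.81 ± 0.45, 1.82 ± 0.30 and 1.90 ± 0.34. Of the exon length of DDIT4 and DDIT3, 41.2% and 31.6% lies under exons of the opposite strand, and whether this changed their counts was not tested.

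In total 13 genes passed, all higher in azaC-treated AAVS1, with 535 genes at an unadjusted p under 0.05. Of 33 measured genes of the stress response list, 8 rose, 0 fell and 25 did not pass, or 17 rose when adjusted over the list alone, and the list as a set rose (mean 0.98, camera adjusted p = 8.5e-08 with an estimated correlation). TRIB3 (1.06, adjusted p = 0.743) and PPP1R15A (0.79, adjusted p = 0.99) did not pass, and ASNS had 0 to 4 counts per library and was not tested in any comparison. Of 14 amino acid transporters 0 passed, 2 adjusted over the list alone, and the set rose (mean 0.40, adjusted p = 0.00127 with an estimated correlation). The amino acid synthesis and tRNA synthetase sets rose only with the preset correlation (adjusted p = 0.235 and 0.228 with an estimated correlation), as did NRF2 targets (adjusted p = 0.246 with an estimated correlation), and heat shock genes were lower as a set only in the same sense (mean −0.39, adjusted p = 0.228 with an estimated correlation). PCK2 (1.42), PMAIP1 (1.36) and KRI1 (1.30) complete the 10 largest, and each lost its call without single libraries. For PCK2 these were untreated replicates 1 and 2 and azaC replicate 3 (adjusted p = 0.0838, 0.116 and 0.0568, range over alternatives 0.000653 to 1). For PMAIP1 they were untreated replicates 1 and 3 and azaC replicate 2 (0.13, 0.0708 and 0.112, range 6.52e-05 to 1), and for KRI1 untreated replicate 2 and azaC replicates 2 and 3 (0.63, 0.0789 and 0.108, range 0.00118 to 1). Leaving out untreated replicate 3 raised the count to 22, and with no filter on low counts it was 30. Fitted to the 6 AAVS1 libraries alone, 4 genes passed, and ATF3 (adjusted p = 0.152, range 9.05e-16 to 0.152), DDIT3 (0.224, range 1.04e-07 to 0.224) and CEBPB (0.935, range 2.48e-05 to 0.935) no longer did. CEBPB also did not pass with GC-corrected offsets (0.299).

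In RNF25 KO cells, azaC raised the same program to higher levels. SESN2 rose from 69.9 ± 1.92 to 485 ± 23.1 CPM, a log2 change of 2.79 ± 0.18 (adjusted p = 1.89e-15), and DDIT3 from 20.1 ± 3.40 to 172 ± 39.9 CPM (3.10 ± 0.29, adjusted p = 3.71e-10). CHAC1 rose by 4.93 ± 0.52 to 175 ± 8.57 CPM, DDIT4 by 4.19 ± 0.37, ATF3 by 3.44 ± 0.42, STC2 by 2.69 ± 0.24, the pseudokinase gene TRIB3 by 1.90 ± 0.31, CEBPB by 2.21 ± 0.31 and the immediate early gene JUN by 2.56 ± 0.46. Amino acid supply genes rose with them, among them the transporters SLC38A2 (1.56 ± 0.18), SLC3A2 (1.18 ± 0.15) and SLC7A11 (1.73 ± 0.24), and CTH (2.13 ± 0.32), which makes cysteine from cystathionine. PPP1R15A, a regulator of eIF2 dephosphorylation, rose by 1.64 ± 0.39 (adjusted p = 0.0288) but not without untreated replicates 1, 2 and 3 or azaC replicates 1 and 2 (0.204, 0.0505, 0.187, 0.074 and 0.177, range over alternatives 0.000532 to 0.204). HSPA8, the constitutive cytosolic Hsp70 chaperone (ENSG00000109971, chromosome 11, 123057489 to 123063230), fell by 1.04 (adjusted p = 0.0188).

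Among 33 stress response genes 22 rose and 11 did not pass, or 29 rose when adjusted over the list alone (mean 1.67, adjusted p = 5.42e-13 with an estimated correlation). Of the transporters 7 of 14 rose (10 adjusted over the list alone, mean 0.90, adjusted p = 1.7e-09 with an estimated correlation). Synthesis genes had 5 of 13 higher (7 adjusted over the list alone, mean 0.68, adjusted p = 2.58e-05 with an estimated correlation), and immediate early genes 2 of 16, JUN and IER2 (3 adjusted over the list alone, mean 0.75, adjusted p = 0.00139 with an estimated correlation). Of 20 tRNA synthetases only CARS1 rose (1.102 ± 0.19, 4 adjusted over the list alone), and the set's call was lost (adjusted p = 0.094 with an estimated correlation). Of 14 heat shock genes HSPA8 fell and 13 did not pass, 6 fell when adjusted over the list alone, and the set fell (mean −0.75, adjusted p = 0.0186 with an estimated correlation). HERPUD1 (1.74 ± 0.20) and XBP1 (1.51 ± 0.26) rose among 21 ER genes whose median was −0.07 and mean 0.17 (camera adjusted p = 0.261), and GADD45A (1.61 ± 0.33) rose among 18 p53 targets (mean 0.25, camera adjusted p = 0.0722).

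In the remaining lists no member passed in azaC-treated RNF25 KO cells except SLC7A11 among 15 NRF2 targets (mean 0.30, adjusted p = 0.133 with an estimated correlation). Means were 0.13 for 11 of 25 interferon-stimulated genes measured (median −0.26) and 0.03 for 24 S phase genes (test direction down). They were −0.17 for 20 G2/M genes (adjusted p = 0.473 with an estimated correlation) and 0.02 for 24 collision and quality control genes (2 higher when adjusted over the list alone, median −0.03, test direction down). Means of 0.18 for 13 autophagy genes, 0.09 for 18 pyrimidine and nucleoside genes (median −0.05) and 0.10 for 76 ribosomal protein genes were found, with 0.01 for 26 ribosome biogenesis genes (median −0.07), −0.02 for 20 cholesterol genes, and −0.25 for 13 mitochondrial mRNAs (adjusted p = 0.44 with an estimated correlation). Of the methylation-silenced germline genes 1 of 19 could be tested (DAZL 0.06, adjusted p = 0.987). None of 14 haematopoietic or 12 epithelial markers could be tested, and of 12 neural markers only MAP2, which did not change with azaC. The mitochondrial share of RNF25 KO azaC replicate 2 was below that of the other libraries, so the mitochondrial list carries that library's deviation.

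Together 50 genes were higher and 2 lower in azaC-treated RNF25 KO cells, with 1031 at an unadjusted p under 0.05. The count changed to 34 without untreated replicate 1, to 90, 29 and 79 without azaC replicates 1, 2 and 3, to 110 with no filter and to 26 in a fit to the 6 RNF25 KO libraries alone. Of 24 named genes 14 stayed past the threshold with each single library left out, and 1 of these, SLC1A4, did not in the fit to the 6 RNF25 KO libraries (adjusted p = 0.053, range over alternatives 0.00011 to 0.053). HSPA8 lost its call without untreated replicates 1 and 2 and azaC replicates 1 and 3 (adjusted p = 0.23, 0.0957, 0.0839 and 0.102, range over alternatives 1.74e-05 to 0.23). CARS1 lost it without azaC replicate 2 (0.0691, range 1.4e-05 to 0.105), as did IER2 (0.0703, range 7.39e-05 to 0.186). The growth factor gene GDF15 rose by 3.14 ± 0.74 (adjusted p = 0.0301) but not without untreated replicates 1 and 2 or azaC replicates 2 and 3 (0.239, 0.287, 0.0703 and 0.057, range 1.08e-10 to 0.287).

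**Figure D1:**
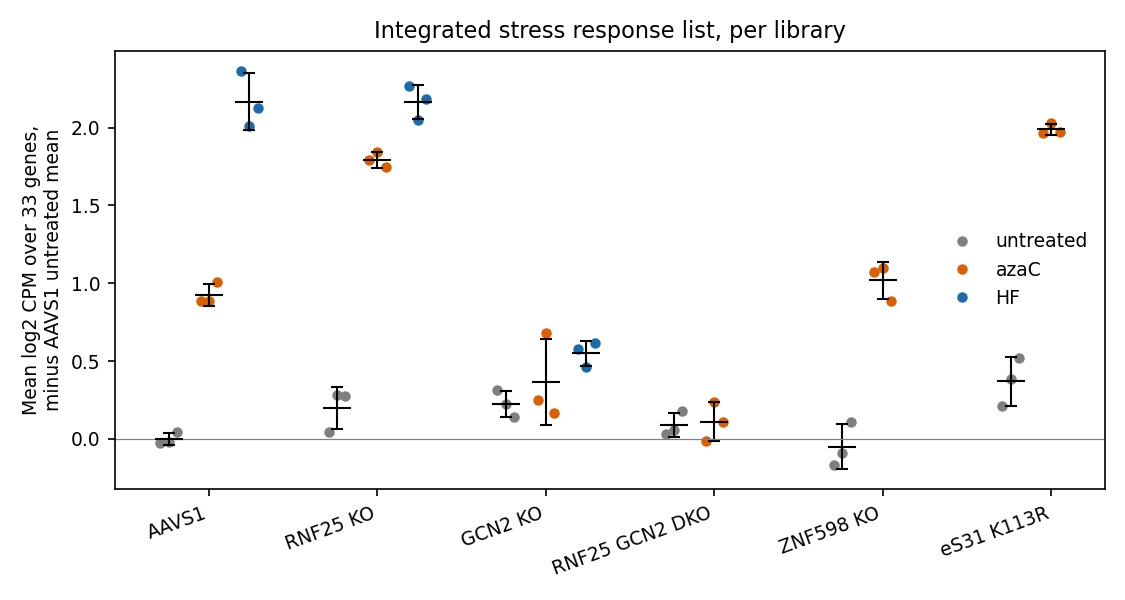
Mean log2 CPM over the 33 measured genes of the integrated stress response list, per library (points), relative to the mean of untreated AAVS1, for each genotype and treatment. Lines are means and bars SD (n = 3), and after azaC the means were 0.93 in AAVS1, 1.79 in RNF25 KO, 1.99 in eS31 K113R, 1.02 in ZNF598 KO, 0.37 in GCN2 KO and 0.11 in RNF25 GCN2 DKO.

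The azaC responses of RNF25 KO and AAVS1 cells differed for the stress response genes as a set. The list rose by 0.69 more on average in RNF25 KO (adjusted p = 7.77e-05 with an estimated correlation), transporters by 0.50 (adjusted p = 0.000124 with an estimated correlation) and synthesis genes by 0.47 (adjusted p = 0.00577 with an estimated correlation). Per library, the stress response list stood 1.79 ± 0.05 (SD, n = 3) above untreated AAVS1 in azaC-treated RNF25 KO and 0.93 ± 0.07 in azaC-treated AAVS1, and untreated RNF25 KO stood at 0.20 ± 0.13. For single genes the difference was not detected at this depth. No gene passed in edgeR, with 305 at an unadjusted p under 0.05, and 0 passed in DESeq2 and in limma-voom. The smallest adjusted p was that of SESN2, which rose by 1.15 ± 0.25 more in RNF25 KO (adjusted p = 0.345). DDIT3 (1.28), PPP1R15A (0.85), TRIB3 (0.84), ATF3 (0.63) and CHAC1 (−0.02) did not pass either. Adjusted over the list alone, 3 of 33 stress response genes, 6 of 14 transporters and 0 of 13 synthesis genes passed. With no filter on low counts 6 genes passed, all lower in RNF25 KO. Simulated differences of 4-fold in this comparison were recovered for 64.9% of genes, and those of 2-fold for 15.2%. The simulations held no deviation shared by replicate number and no GC slope, so recovery in the real libraries may differ.

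In GCN2 KO cells the stress response genes did not rise with azaC. SESN2 stood at 68.4 ± 8.08 CPM untreated and 71.7 ± 20.6 CPM after azaC (0.07, adjusted p = 1), DDIT3 at 18.7 ± 6.58 and 20.5 ± 6.90 CPM (0.10), and CHAC1 at 3.78 ± 2.60 and 8.34 ± 12.1 CPM (1.22). ATF3 (0.56), TRIB3 (0.35) and PPP1R15A (0.11) did not pass either, and no gene of any list passed. The stress response list had a mean of 0.22 (camera adjusted p = 0.0798). Without azaC replicate 2 that mean was −0.0444 (adjusted p = 0.818), and without azaC replicate 1 or 3 it was 0.243 or 0.296 and passed (adjusted p = 0.0338 and 0.00924). In the libraries labelled RNF25 GCN2 DKO the values were 0.16 for SESN2, −0.56 for CHAC1, 1.16 for ATF3, 0.10 for TRIB3 and 0.67 for PPP1R15A (each adjusted p = 1), and the list mean was −0.03 (camera adjusted p = 0.963). In edgeR 0 genes passed in either line, with 405 genes in GCN2 KO and 291 in the DKO at an unadjusted p under 0.05, and DESeq2 and limma-voom also gave 0. With no filter 1 gene passed in the DKO.

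The difference from AAVS1 was tested directly. The stress response list rose less in GCN2 KO than in AAVS1 by a mean of −0.76 (adjusted p = 4.76e-05 with an estimated correlation, 10 of 33 genes lower when adjusted over the list alone). Among single genes SESN2 alone passed (−1.57 ± 0.26, adjusted p = 0.00231), with 280 genes at an unadjusted p under 0.05. In a fit to the 12 libraries compared it did not pass (0.588, range over alternatives 3.66e-05 to 0.588). The count became 2 without AAVS1 untreated replicate 1 and 5 without GCN2 KO azaC replicate 2. In the DKO the list rose less than in AAVS1 by −1.01 (adjusted p = 9.22e-06 with an estimated correlation), and 5 genes passed, all lower. These were SESN2 (−1.49 ± 0.26, adjusted p = 0.00355), DDIT4 (−3.49 ± 0.58, adjusted p = 0.00355), CHAC1 (−5.51 ± 0.99), STC2 (−1.85 ± 0.35) and PCK2 (−1.75 ± 0.36). Without DKO untreated replicate 2 the count was 2 and CHAC1 (adjusted p = 1) and STC2 (0.128) were lost, without DKO azaC replicate 1 it was 3 and STC2 was lost (0.0992), and PCK2 was lost in most such fits (range over alternatives 0.00814 to 0.911). SESN2 did not pass in a fit to the 12 libraries compared (0.0849).

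Against RNF25 KO, the libraries labelled DKO showed a smaller azaC response in 13 genes, all lower, with 610 at an unadjusted p under 0.05. SESN2 differed by −2.64 ± 0.25 (adjusted p = 2.25e-09), DDIT4 by −4.63 ± 0.56 (adjusted p = 7.42e-07), STC2 by −2.62 ± 0.35 (adjusted p = 6.49e-06), DDIT3 by −3.11 ± 0.46 (adjusted p = 6.47e-05) and CHAC1 by −5.48 ± 0.92 (adjusted p = 0.00056, and 0.419 without DKO untreated replicate 2, range over alternatives 1.83e-15 to 0.419). Of the stress response list 9 of 33 were lower (25 adjusted over the list alone, mean −1.70, adjusted p = 1.04e-10 with an estimated correlation), as were 3 of 14 transporters (8 adjusted over the list alone, mean −0.88) and 0 of 13 synthesis genes (7 adjusted over the list alone, mean −0.59). Against GCN2 KO no difference was detected. No gene passed in edgeR, DESeq2 or limma-voom (280 at an unadjusted p under 0.05), and the stress response list differed by −0.24 (camera adjusted p = 0.296). EIF2AK4 mRNA in the DKO libraries was near that of AAVS1, as given above.

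In ZNF598 KO cells azaC raised 13 genes and lowered 0, with 331 at an unadjusted p under 0.05. SESN2 rose from 46.9 ± 1.24 to 217 ± 26.9 CPM (2.21 ± 0.18, adjusted p = 1.21e-11), CHAC1 by 5.25 ± 0.60, DDIT4 by 3.54 ± 0.40, DDIT3 by 2.60 ± 0.32, ATF3 by 2.38 ± 0.41 and STC2 by 2.33 ± 0.25. Of the stress response list 7 of 33 rose (22 adjusted over the list alone, mean 1.14, adjusted p = 2.33e-11 with an estimated correlation), and of 14 transporters SLC38A2 rose (1.00 ± 0.18, 3 adjusted over the list alone, mean 0.45). JUN rose by 2.54 ± 0.48 but not without untreated replicate 1 or azaC replicate 2 (adjusted p = 0.125 and 0.107, range over alternatives 3.14e-16 to 0.125), and SLC38A2 did not pass without untreated replicate 3 (0.0794, range 2.96e-05 to 0.0794). The difference from AAVS1 was not detected. No gene passed in edgeR (341 at an unadjusted p under 0.05), DESeq2 or limma-voom, and the list differed by 0.15 (camera adjusted p = 0.252). The list difference passed without ZNF598 KO untreated replicate 3 (0.385, adjusted p = 0.0399), AAVS1 azaC replicate 3 (0.233, adjusted p = 0.0273) or ZNF598 KO azaC replicate 3 (0.197, adjusted p = 0.0258), and with GC-corrected offsets (0.265, adjusted p = 0.00329).

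In eS31 K113R cells azaC raised 52 genes and lowered 5, with 578 at an unadjusted p under 0.05. SESN2 rose from 74.5 ± 8.87 to 617 ± 25.1 CPM (3.04 ± 0.18, adjusted p = 9.24e-17), DDIT4 by 4.15 ± 0.36, ATF3 by 3.76 ± 0.43, DDIT3 by 3.13 ± 0.30, STC2 by 2.56 ± 0.24 and TRIB3 by 2.49 ± 0.33. HSPA8 fell by 1.42 (adjusted p = 0.000216) and the mitochondrial tRNA gene MT-TP by 1.12 (adjusted p = 4e-04). CHAC1 stood lower than in the other responding lines, at 13.97 ± 3.03 CPM, from 1.17 ± 1.15 CPM untreated (3.47 ± 0.81, adjusted p = 0.025). Of the stress response list 20 of 33 rose (31 adjusted over the list alone, mean 1.68, adjusted p = 4.27e-15 with an estimated correlation). Of transporters 5 of 14 rose (9 adjusted over the list alone, mean 0.83), and of synthesis genes 5 of 13 (7 adjusted over the list alone, mean 0.57). Immediate early genes had 3 of 16 higher (4 adjusted over the list alone, mean 0.69), and tRNA synthetases GARS1 (0.91 ± 0.17, 2 of 20 adjusted over the list alone, mean 0.27). Of 14 heat shock genes 3 fell (8 adjusted over the list alone, mean −0.81, adjusted p = 0.00514 with an estimated correlation). The transporter, synthesis, immediate early and tRNA synthetase calls also held with an estimated correlation.

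The count in eS31 K113R was 34 without untreated replicate 1 and 34 without azaC replicate 2, and 26 when only the untreated library with the eS31 K113R title was kept. CHAC1 lost its call without untreated replicates 1 and 2 and azaC replicates 1 and 3 (adjusted p = 0.232, 0.154, 0.101 and 0.0634, range over alternatives 1.7e-07 to 0.297). Against AAVS1 the stress response list rose by 0.70 more (adjusted p = 3.45e-05 with an estimated correlation, 8 of 33 adjusted over the list alone) and transporters by 0.44 (adjusted p = 0.00169 with an estimated correlation). Untreated lines also differed from AAVS1 over chromosome regions, as given below for X in eS31 K113R and GCN2 KO. What these differences add to the drug responses was not tested, and no second clone of a genotype was compared. SESN2 was the single gene that passed, by 1.40 ± 0.25 (adjusted p = 0.012), with 412 at an unadjusted p under 0.05. It lost that call without AAVS1 untreated replicates 1 and 3 (adjusted p = 0.0606 and 0.0647), eS31 K113R untreated replicates 1 and 3 (0.134 and 0.064), AAVS1 azaC replicates 1 and 2 (0.108 and 0.0919) or eS31 K113R azaC replicate 1 (0.059), with a range over alternatives of 0.000137 to 0.269. Against RNF25 KO no difference in the azaC response was detected. No gene passed in edgeR (482 at an unadjusted p under 0.05), DESeq2 or limma-voom, and the list differed by 0.01 (camera adjusted p = 0.711).

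The genes raised by azaC overlapped between lines whose libraries were all different. AAVS1 and RNF25 KO shared 12 genes (0.0587 for independent lists), AAVS1 and ZNF598 KO 9 (0.0153), AAVS1 and eS31 K113R 11 (0.061), and RNF25 KO and eS31 K113R 34 (0.235). Of the 50 genes higher with azaC in RNF25 KO, 40 were also higher with HF in AAVS1 (0.528 for independent lists), and of the 52 in eS31 K113R 43 were (0.549). Among the latter were the amino acid genes SLC38A2, SLC3A2, SLC7A11, CTH and GPT2, and HERPUD1 and XBP1.

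**Figure D2:**
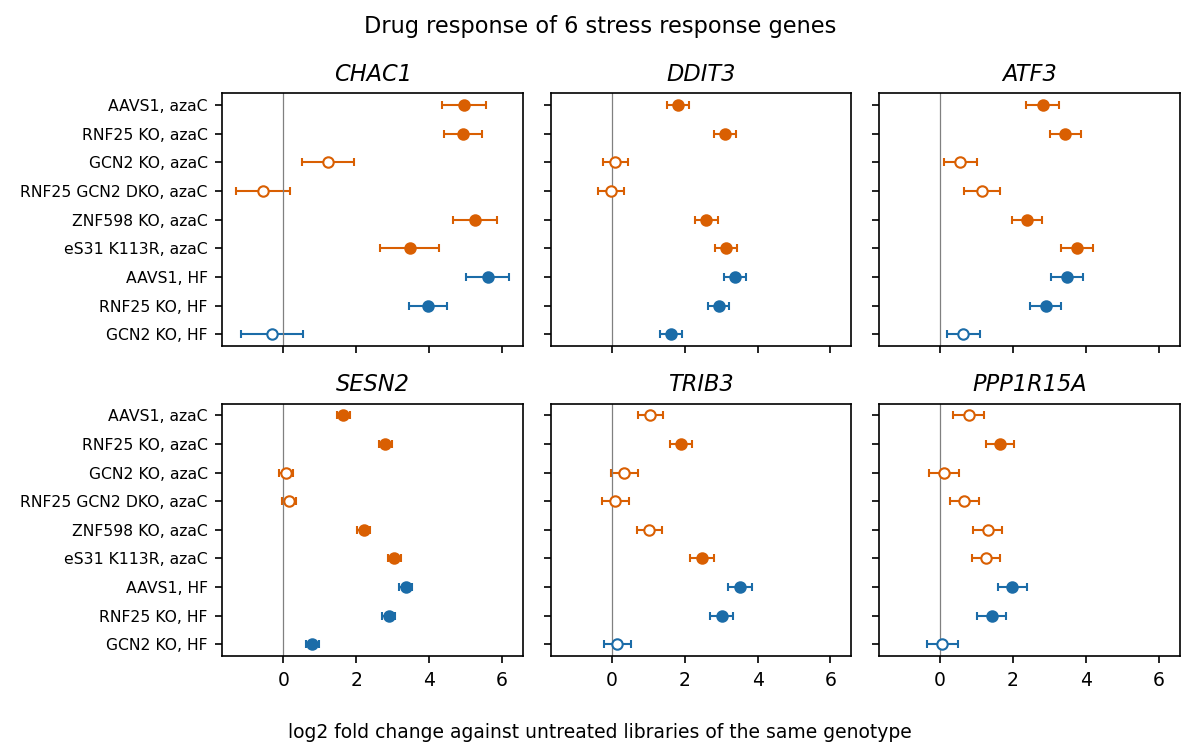
Log2 fold change against untreated libraries of the same genotype for 6 genes of the stress response list after azaC (orange) and HF (blue), with SE from edgeR as bars (n = 3 libraries per group). Filled points passed at an adjusted p under 0.05, and SESN2 ranged from 0.07 in GCN2 KO after azaC to 3.35 in AAVS1 after HF.

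HF raised the stress response program in AAVS1 and RNF25 KO and lowered heat shock genes. A few cholesterol genes also fell, and as a set they held with an estimated correlation in RNF25 KO but not in AAVS1. In AAVS1, SESN2 rose by 3.35 ± 0.18 to 581 ± 109 CPM (adjusted p = 4.59e-18), DDIT3 by 3.38 ± 0.30, CHAC1 by 5.6005 ± 0.60, GDF15 by 5.50 ± 0.89, DDIT4 by 4.25 ± 0.39, TRIB3 by 3.51 ± 0.33, ATF3 by 3.49 ± 0.44 and STC2 by 3.31 ± 0.25. HSPA8 dropped from 1645 ± 335 to 171 ± 34.1 CPM (−3.26 ± 0.26, adjusted p = 1.18e-12), the co-chaperone genes DNAJB1 and DNAJA1 by −2.74 ± 0.42 and −1.89 ± 0.22, and the inducible Hsp70 gene HSPA1A, whose reads may be shared with its near-identical copy HSPA1B, by −3.54 ± 0.58. The sterol enzyme gene MSMO1 fell by 1.81 and the dioxygenase gene JMJD6 by 1.79. In RNF25 KO the values were 2.89 ± 0.18 for SESN2, 2.94 ± 0.29 for DDIT3, 3.97 ± 0.52 for CHAC1, 4.62 ± 0.74 for GDF15, −3.47 ± 0.26 for HSPA8, −2.48 ± 0.41 for DNAJB1 and −2.13 ± 0.22 for DNAJA1. NUPR1, a stress-inducible chromatin factor, went from 3 to 62 counts over the 3 libraries in AAVS1 and from 1 to 58 in RNF25 KO, and ARHGAP9 from 3 to 48 and from 1 to 35.

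HF raised 27 of 33 stress response genes in AAVS1 (30 adjusted over the list alone, mean 2.28, adjusted p = 2.52e-14 with an estimated correlation) and 29 in RNF25 KO (31 adjusted over the list alone, mean 2.06). Of transporters 7 of 14 rose in each (10 in AAVS1, and 11 with 1 lower in RNF25 KO, adjusted over the list alone). Synthesis genes had 7 of 13 higher in each (7 adjusted over the list alone), among them CTH (2.28 ± 0.30 and 3.14 ± 0.32), and tRNA synthetases 6 of 20 and 4 of 20 (11 and 7 adjusted over the list alone), among them CARS1 (1.38 ± 0.19 in AAVS1). Of 14 heat shock genes 6 fell in each line (9 and 11 adjusted over the list alone, means −1.39 and −1.43), and each of these list calls held with an estimated correlation. Of 20 cholesterol genes 4 fell in AAVS1 (7 adjusted over the list alone, mean −0.49, adjusted p = 0.0553 with an estimated correlation) and 5 in RNF25 KO (7 adjusted over the list alone, mean −0.64, adjusted p = 0.0242 with an estimated correlation). ER genes moved both ways, with HERPUD1 (1.86 ± 0.20) and XBP1 (1.60 ± 0.26) higher and the ER chaperone genes HSPA5 (−0.83 ± 0.16) and MANF (−0.64 ± 0.17) lower in AAVS1. GADD45A was the p53 target that rose (2.19 ± 0.37 in AAVS1, adjusted p = 0.46 with an estimated correlation for the set).

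In AAVS1 117 genes were higher and 54 lower with HF (1236 at an unadjusted p under 0.05), and in RNF25 KO 136 and 56 (1207). The count fell to 101 without AAVS1 HF replicate 1, and in RNF25 KO to 123 without untreated replicate 1, 119 without HF replicate 1 and 110 without HF replicate 2. NUPR1 in AAVS1 lost its call without untreated replicates 1 and 3 and HF replicate 3 (adjusted p = 0.0698, 0.0666 and 0.0526, range over alternatives 0.00341 to 0.0698), and PPP1R15A (1.98, adjusted p = 0.00163) without HF replicate 1 (0.0658, range 5.13e-06 to 0.175). ARHGAP9 stopped passing without untreated replicates 1, 2 and 3 and HF replicates 1 and 2, both in AAVS1 (adjusted p = 0.106, 0.117, 0.143, 0.341 and 0.0642, range 0.00915 to 0.341) and in RNF25 KO (0.189, 0.088, 0.206, 0.11 and 0.241, range 0.0141 to 0.241). The lines, which share no libraries, had 72 higher (1.44 for independent lists) and 27 lower genes (0.273) in common. No gene differed in its HF response between them in edgeR (291 at an unadjusted p under 0.05), DESeq2 or limma-voom, and 2 did with no filter.

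In GCN2 KO cells HF left most stress response genes near their untreated levels and still lowered heat shock genes. CHAC1 (−0.31), TRIB3 (0.16), ATF3 (0.64) and PPP1R15A (0.07) did not pass, while DDIT3 rose by 1.62 ± 0.31 (adjusted p = 0.00193), from 18.7 ± 6.58 to 58.5 ± 4.41 CPM. HSPA8 fell by 3.05 to 204 ± 63.6 CPM (adjusted p = 2.28e-11), DNAJB1 by 2.51 and DNAJA1 by 1.99. TXNIP, a regulator of thioredoxin and glucose uptake, rose by 3.17 ± 0.35, as did the immediate early genes KLF10 (2.4973 ± 0.36) and IER5 (1.45 ± 0.27) and the p53 target GADD45A (2.17 ± 0.39), and the phosphatase gene DUSP2 (−3.07 ± 0.55), the transcription factor gene SOX8 (−2.70 ± 0.52) and BRD3OS (−2.85 ± 0.47) fell. Just 3 of 33 stress response genes rose (5 adjusted over the list alone, mean 0.27), and the set's call was lost (adjusted p = 0.112 with an estimated correlation). Of the 3, SESN2 (0.80, adjusted p = 0.0109) lost its call without untreated replicate 3 and HF replicates 1 and 3 (0.118, 0.0663 and 0.126, range over alternatives 0.00222 to 0.126), and SLC3A2 (0.71) without untreated replicates 1 and 2 and HF replicate 2 (0.104, 0.0563 and 0.0532, range 0.000767 to 0.104). Of heat shock genes 5 of 14 fell (10 adjusted over the list alone, mean −1.25, adjusted p = 0.000455 with an estimated correlation), and of immediate early genes 4 of 16 rose (7 adjusted over the list alone, mean 0.74, adjusted p = 0.000455 with an estimated correlation). The cholesterol list had a median of −0.12 and a mean of 0.01, with 0 of 20 past the threshold (1 higher and 3 lower adjusted over the list alone). In all 81 genes were higher and 56 lower (1086 at an unadjusted p under 0.05). The count fell to 56, 68 and 68 without untreated replicates 1, 2 and 3 and to 44 and 56 without HF replicates 1 and 2. With HF in AAVS1, 17 higher (0.855 for independent lists) and 11 lower genes (0.273) were shared.

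The HF response of GCN2 KO differed from that of AAVS1 in 37 genes, 30 lower and 7 higher, with 797 at an unadjusted p under 0.05. Among them were CHAC1 (−5.91 ± 1.15, adjusted p = 0.0029), DDIT4 (−4.75 ± 0.66, adjusted p = 8.16e-06), TRIB3 (−3.35 ± 0.51, adjusted p = 5.1e-05) and the noncoding RNA LINC00662 (−3.13 ± 0.42, adjusted p = 3.15e-06), and HES1 (1.83 ± 0.34, adjusted p = 0.00139) and MCL1, an inhibitor of apoptosis (1.2496 ± 0.23, adjusted p = 0.00139), responded in the other direction. CHAC1 lost its call without GCN2 KO untreated replicates 1 and 2 (adjusted p = 0.109 and 0.0635, range over alternatives 4.33e-11 to 0.109). Of the stress response list 14 of 33 responded less in GCN2 KO (26 adjusted over the list alone, mean −2.00, adjusted p = 5.94e-11 with an estimated correlation). Transporters had 2 of 14 lower (9 adjusted over the list alone, mean −1.03), synthesis genes 5 of 13 (7 adjusted over the list alone, mean −0.82) and tRNA synthetases 0 of 20 (7 adjusted over the list alone, mean −0.45), and each of these held with an estimated correlation. The heat shock list did not differ between the lines (mean 0.14, camera adjusted p = 0.462).

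Against HF, azaC in AAVS1 left the chaperone genes higher and the stress response genes lower. HSPA8 was higher with azaC by 2.64 ± 0.25 (adjusted p = 1.93e-09) and DNAJB1 by 2.30 ± 0.42, and TRIB3 (−2.45 ± 0.30, adjusted p = 9.41e-07), SLC7A11 (−1.99 ± 0.23), SLC6A9 (−2.05 ± 0.39) and TSC22D3, a glucocorticoid-induced leucine zipper gene (−1.97 ± 0.27), were lower. Of the stress response list 20 of 33 were lower (27 adjusted over the list alone, mean −1.30, adjusted p = 7.24e-11 with an estimated correlation). Transporters had 6 of 14 lower (7 adjusted over the list alone, mean −0.70), synthesis genes 6 of 13 (7 adjusted over the list alone, mean −0.64) and tRNA synthetases 4 of 20 (9 adjusted over the list alone, mean −0.32). In contrast 4 of 14 heat shock genes (6 adjusted over the list alone, mean 1.00) and 4 of 20 cholesterol genes (7 adjusted over the list alone, mean 0.57) were higher. In RNF25 KO the drugs were closer on the stress response list, with 4 genes lower with azaC (9 lower and 1 higher adjusted over the list alone, mean −0.39, adjusted p = 0.04 with an estimated correlation), and HSPA8 was again higher with azaC (2.43 ± 0.25, adjusted p = 2.24e-08). Whether these contrasts differ between the lines was not tested. In AAVS1 34 genes were higher and 76 lower (1047 at an unadjusted p under 0.05). The count was 59, 55 and 58 without azaC replicates 1, 2 and 3 and 51 without HF replicate 1 or 2. In RNF25 KO 48 were higher and 33 lower (1530). The count was 215, 17 and 137 without azaC replicates 1, 2 and 3, and 36 and 3 without HF replicates 1 and 2. Of 18 named genes there, HSPA8 and DNAJA1 were the 2 that stayed past the threshold in all such fits.

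Across 8304 genes, which are not independent replicates, the fold changes of azaC and HF correlated with r = 0.532 in AAVS1, where both share the untreated libraries and unchanged groups simulated against such controls gave 0.498. The covariance was 0.0823 against 0.0525 simulated, a difference of 0.0298. In RNF25 KO r was 0.454 against 0.507 simulated, and the covariance 0.0794 against 0.0527. With no shared library, azaC in RNF25 KO and HF in AAVS1 correlated with r = 0.338 (simulated 0.000343, covariance 0.0613), and azaC in GCN2 KO and HF in AAVS1 with r = 0.0979 (simulated −0.00316, covariance 0.0132). The simulated counts varied independently between genes and held no library-wide deviation such as a slope on GC content. Such slopes were −0.4912 in AAVS1 untreated replicate 2 and 0.3389 in RNF25 KO azaC replicate 2. Their part in these correlations was not tested, so r does not measure a shared drug response alone. Within AAVS1 the drugs shared 12 higher genes (0.137 for independent lists) and within RNF25 KO 40 (0.614), and part of that excess may come from the shared untreated libraries, of which 3 cannot be split into groups of 2.

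Without drug, each edited line differed from AAVS1 in many genes, several of them switched between no counts and clear expression. In RNF25 KO, TCEAL9 went from 0 to 381 counts over the 3 libraries (85.1 ± 14.5 CPM, at least 134-fold higher), the immunoproteasome gene PSMB8 from 0 to 168 counts (at least 58.9-fold), and DCAF12L2 from 0 to 67 (at least 23.1-fold), while PCDHB5 went from 54 counts to 0 (at least 16.8-fold lower) and BMPR1B from 52 to 0 (at least 14.9-fold lower). The libraries labelled DKO shared TCEAL9 (0 to 442 counts, at least 134-fold) and PSMB8 (0 to 210, at least 66.7-fold). GCN2 KO had more of the growth factor gene BMP7 (0 to 155 counts, at least 64.6-fold) and LYPD1 (0 to 42, at least 18.1-fold) and less of the adhesion gene CADM1 (−4.32 ± 0.62, adjusted p = 9.82e-06). ZNF598 KO had more BMP7 (0 to 282, at least 85.2-fold), MYOM1 (3 to 619 counts) and TPM2 (6.95 ± 0.52, adjusted p = 4.44e-13) and less CTSF (209 counts to 1). The eS31 K113R libraries had more CGAS, the cytosolic DNA sensor (0 to 41, at least 14.4-fold), and LRRC7 (0 to 32, at least 11.4-fold). CGAS also passed as higher in RNF25 KO (adjusted p = 0.00294), the DKO libraries (0.0347) and ZNF598 KO (0.0378), and PSMB8 in GCN2 KO (0 to 33, at least 13.7-fold). In all 5 lines 14 genes were higher, among them ALX4 and FAM111A, and as the same AAVS1 libraries serve each comparison, a low level in AAVS1 would show in all of them. In the fixed lists few genes differed. NQO1, a quinone reductase and NRF2 target, was higher in RNF25 KO (1.68), GCN2 KO (1.17), the DKO libraries (1.33) and eS31 K113R (1.80), while ME1, another NRF2 target, was lower in RNF25 KO (−2.29) and the DKO libraries (−2.37). The 15 NRF2 targets as a set did not pass in RNF25 KO (mean 0.31, camera adjusted p = 0.217), and in eS31 K113R only with the preset correlation (mean 0.53, adjusted p = 0.101 with an estimated correlation). The stress response list was higher as a set in eS31 K113R only with the preset correlation (mean 0.40, 2 of 33 higher, 5 adjusted over the list alone, adjusted p = 0.101 with an estimated correlation). With the single untreated library titled eS31 K113R that mean was −0.0250. In log2 CPM with a prior count of 2, that library stood 0.209 above the untreated AAVS1 mean, where AAVS1 libraries reached 0.047. The sign thus depended on the measure. The neural marker MAP2 was lower in RNF25 KO (−3.10, adjusted p = 0.00365).

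Counts of genes higher and lower against AAVS1 were 105 and 74 in RNF25 KO (1076 at an unadjusted p under 0.05), 78 and 38 in GCN2 KO (1061), 96 and 61 in the DKO libraries (1017), 63 and 40 in ZNF598 KO (988) and 131 and 187 in eS31 K113R (1306). In GCN2 KO the count was 74 without AAVS1 replicate 2 or GCN2 KO replicate 3, in the DKO 99 without its replicate 2, in eS31 K113R 209 without its replicate 1, and in ZNF598 KO 65 and 63 without AAVS1 replicates 1 and 2 and 67 without ZNF598 KO replicate 1 or 3. When only the groups compared were fitted, the counts were 53, 15, 48, 24 and 65 in that order, and LYPD1 no longer passed (adjusted p = 0.0537). With the single eS31 K113R title LRRC7 did not pass (0.405). All 5 comparisons use the same AAVS1 libraries. RNF25 KO and the DKO shared 72 higher and 41 lower genes (0.91 and 0.407 for independent lists), and part of that excess may come from the shared controls.

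Many of these differences lay together on chromosomes. In eS31 K113R, genes of chromosome X were lower, with a median of −0.88 over 130 genes from 1 to 80 Mb and −0.86 over 119 genes from 100 to 160 Mb, and 66 lower genes that passed lay in each of these regions. In RNF25 KO and in the DKO libraries, genes in the first 10 Mb of chromosome 4 were lower (−0.96 and −0.89 over 33 genes) and genes from 30 to 50 Mb (0.64 over 26 genes) or 10 to 50 Mb (0.68 over 48 genes) were higher. GCN2 KO had higher genes from 10 to 20 Mb of chromosome 8 (0.86 over 14) and lower genes from 1 to 60 Mb of X (−0.52 over 91), and ZNF598 KO lower genes from 50 to 60 Mb of chromosome 16 (−0.56 over 29). Bins of 10 Mb with at least 8 genes were used, and 27 of 1315 had a median beyond 0.4 in size. In ZNF598 KO the other bins from 40 Mb to the end of chromosome 16 were lower too without passing it (medians −0.30, −0.30, −0.38 and −0.39). RNF25 KO likewise had higher genes in the bins from 10 to 30 Mb of chromosome 4 without passing 0.4 (medians 0.3048 and 0.3984). In GCN2 KO the bins used past 60 Mb of X were lower too (medians −0.174 to −0.310). Its bin from 20 to 30 Mb of chromosome 8 was higher (0.245), and none of these passed 0.4. The bin settings were chosen after the clustering had been seen.

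**Figure D3:**
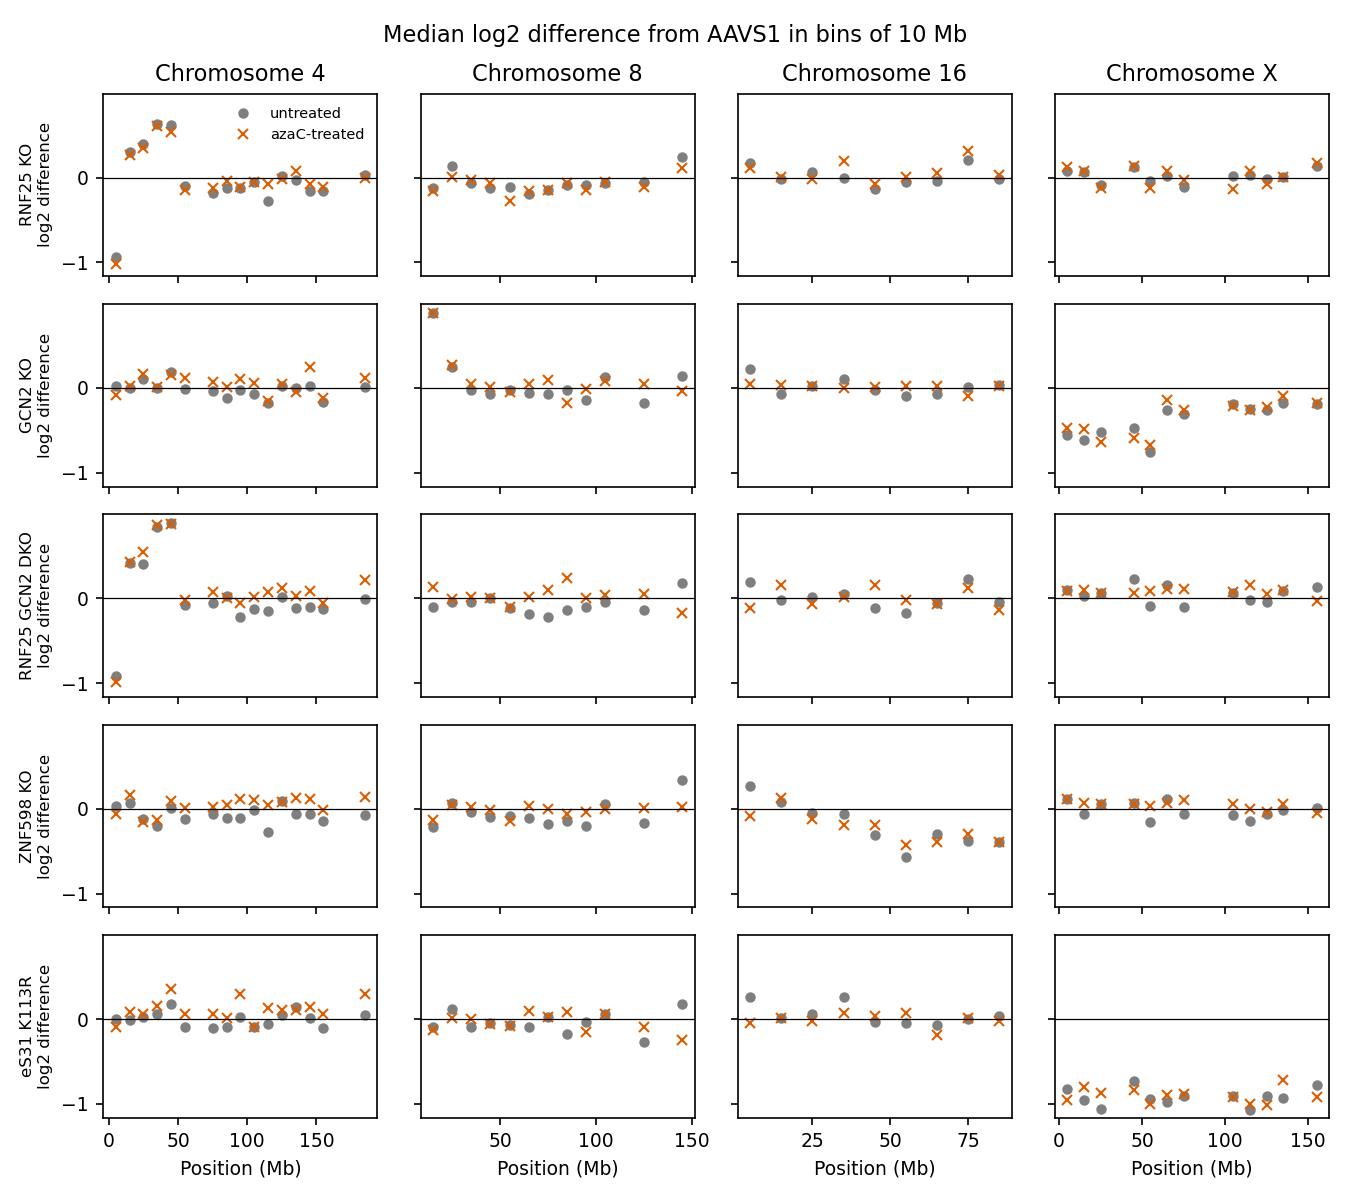
Median log2 difference from AAVS1 of the genes in bins of 10 Mb along chromosomes 4, 8, 16 and X, for the 5 edited lines, in untreated (grey) and azaC-treated libraries (orange). The shifts of X in eS31 K113R (−0.88 and −0.86) and of the first 10 Mb of chromosome 4 in RNF25 KO (−0.96) stand at similar values in treated and untreated cells.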

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

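The tests of copy number and of mixed RNA below were chosen after the results they concern were seen, as were the bin settings of the regions. The GC-corrected offsets were added after the data were examined, and what they would show for these patterns was written before those values were seen. The tests of chance for the regions and of other groupings of the libraries were also set before their values were seen.

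The response to azaC differed between lines by the test of the difference itself. Compared with AAVS1, the integrated stress response list rose by a mean log2 difference of 0.690 more in RNF25 KO and 0.699 more in eS31 K113R, and by −0.765 in GCN2 KO and −1.01 in the libraries labelled DKO. Amino acid transporters differed by 0.499 in RNF25 KO, 0.437 in eS31 K113R and −0.386 in the DKO, and amino acid synthesis genes by 0.470 in RNF25 KO. The DKO against RNF25 KO differed by −1.70 for the stress response list, −0.592 for synthesis genes and −0.885 for transporters. For HF, GCN2 KO against AAVS1 differed by −2.005 for the stress response list, −0.450 for tRNA synthetases, −0.817 for synthesis genes and −1.03 for transporters.

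Single genes also differed between lines. In the azaC response against AAVS1 the 1 gene in GCN2 KO was SESN2 (−1.57), the 1 gene in eS31 K113R was SESN2 (1.40), and the 5 in the DKO were CHAC1 (−5.51), DDIT4 (−3.49), STC2 (−1.85), PCK2 (−1.75) and SESN2 (−1.49). The DKO against RNF25 KO differed in 13 genes, among them CHAC1 (−5.48), DDIT4 (−4.63), DDIT3 (−3.11), SESN2 (−2.64) and STC2 (−2.62). The HF response of GCN2 KO differed in 37 genes. HES1 (1.83), MCL1 (1.2496), TUBB4B (1.14), DDX6 (1.14) and MAPK1IP1L (1.05) were higher, and CHAC1 (−5.91), DDIT4 (−4.75), TRIB3 (−3.35), HRK (−3.30) and LINC00662 (−3.13) lower. TUBB4B, DDX6, MAPK1IP1L and HRK each stopped passing without some single libraries, with adjusted p of up to 0.239 for HRK over its alternatives.

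Other groupings of the libraries were tried for each count, 100 random splits for differences between lines and all 10 splits for comparisons of 2 groups. The random splits regroup lines within each treatment, so the groups they form also hold the differences between untreated lines, which passed in 103 to 318 genes against AAVS1. Counts several times the real one point to such a structure of the samples, whose part in them was not tested, so these splits do not decide whether chance gave the drug differences. The edgeR test of the difference gave an adjusted p of 2.25e-09 for SESN2 in the DKO against RNF25 KO, and the stress response list 1.04e-10 there and 5.94e-11 for HF in GCN2 KO with an estimated correlation. For the GCN2 KO azaC difference 20 of 100 splits gave at least its 1 gene (highest other 83), for the DKO 14 gave at least 5 (392), for eS31 K113R 12 gave at least 1 (522), for the DKO against RNF25 KO 13 gave at least 13 (70), and for the GCN2 KO HF difference 16 gave at least 37 (543). For the 5 differences with 0 genes in edgeR all 100 splits give as many by construction, which decides nothing, and the highest others were 408 for RNF25 KO azaC, 285 for ZNF598 KO, 520 for the DKO against GCN2 KO, 348 for eS31 K113R against RNF25 KO and 134 for RNF25 KO HF. Those 5 had 305, 341, 280, 482 and 291 genes at an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0.

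For comparisons of 2 groups the 10 splits are too few for a share under 0.05. Real counts and the highest of the other splits were 13 and 0 for azaC in AAVS1, 52 and 1 in RNF25 KO, 13 and 0 in ZNF598 KO and 57 and 1 in eS31 K113R. They were 171 and 1 for HF in AAVS1, 192 and 1 in RNF25 KO and 137 and 0 in GCN2 KO. Against AAVS1 they were 179 and 0 for untreated RNF25 KO, 116 and 1 for GCN2 KO, 157 and 0 for the DKO, 103 and 1 for ZNF598 KO and 318 and 4 for eS31 K113R. For azaC against HF they were 110 and 0 in AAVS1 and 81 and 6 in RNF25 KO. In each of these 14 comparisons 1 split, the real one, gave as many genes. For azaC in GCN2 KO and the DKO all 10 splits gave at least the 0 genes found by edgeR (405 and 291 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom), and the highest others were 0 and 1.

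Genes of single chromosome regions differed together between untreated edited lines and AAVS1, in 9 regions. Chance values of the untreated cultures do not account for it, since azaC-treated libraries, all different ones, showed the same shifts with a ratio of at least 0.773 to the untreated medians. GC content does not either, since GC-corrected offsets left a ratio of at least 0.938. A candidate explanation is a change in the number of copies of these regions in single clones. In the least uniform region, on chromosome 4 in the DKO, 79.17% of genes lay on the same side of 0, between the limits set. The other regions had 80.77 to 100%, past the upper limit. DNA was not measured, so this stays open. No second clone of a genotype was compared here.

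Heat shock genes fell with HF in GCN2 KO, where most stress response genes did not rise. The tables argue against RNA of an HF-treated responding line mixed into these libraries, since GCN2 KO showed 92.1% of the AAVS1 fall of heat shock genes (range 42.2 to 103%, 6 genes) while the stress response genes implied a share of 5.93% of such RNA (range −4.05 to 27.1%, 15 genes). With GC-corrected offsets the mean of the heat shock list was −1.24, against −1.25 without. Reads shared between gene copies such as HSPA1A and HSPA1B were not tested. The comparison and the heat shock list were fixed beforehand. This fall argues against a need for a full rise of the stress response genes in the line labelled GCN2 KO. With HF, DDIT3 still rose there (1.62, adjusted p = 0.00193 in edgeR) and EIF2AK4 mRNA stood at 15.9 CPM. A complete loss of GCN2 activity was therefore not shown. GCN2 protein was not measured, and by which route the heat shock genes fell was not tested.

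In GCN2 KO azaC replicate 2 CHAC1 had 40 counts, against 4 and 0 in replicates 1 and 3, and ATF3 66, against 28 and 21. RNA of a responding azaC-treated line mixed into this library does not account for it. For AAVS1 as the source, 10 marker genes gave a share of 4.718%, where CHAC1 needs 28.98%, and for RNF25 KO 22 markers gave 1.08%, where it needs 10.99%. ZNF598 KO (0.857% against 25.7%) and eS31 K113R (0.0869% against 179%) lay further off. This library also had a GC slope of 0.119, against 0.0154 and 0.0401 in replicates 1 and 3. What remains, such as a deviation of the library or a partial response of that culture, was not tested.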

How the results depend on the processing

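The GC-corrected offsets and the fit without the 2 libraries of lowest and highest GC slope were chosen after the data were examined, and the other alternatives before. Scaling by RLE or upper quartile kept each of the 26 counts of genes within 1.5 times and each of the 26 means of the integrated stress response list on its side of 0 and of the threshold. limma-voom kept 25 of the counts, GC-corrected offsets 25 and DESeq2 23. With no filter 12 of the 26 counts moved by over 1.5 times, with only the libraries compared 12, with the replicate block 13, and with the single library titled eS31 K113R 3 of the 4 counts it enters. Leaving out 1 library moved 45 counts and kept 171. The direction of the stress response list after azaC in AAVS1, RNF25 KO, ZNF598 KO and eS31 K113R, and after HF in AAVS1 and RNF25 KO, was the same in each alternative run for it, which did not include DESeq2 or limma-voom. Where a value moved, the cause was not tested unless given.

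With no filter on low counts, azaC called 30 genes in AAVS1 (from 13), 110 in RNF25 KO (from 52) and 1 in the DKO (from 0). Differences in azaC response from AAVS1 called 6 genes in RNF25 KO (from 0), 6 in GCN2 KO (from 1), 8 in the DKO (from 5) and 2 in eS31 K113R (from 1). The DKO against RNF25 KO called 31 (from 13), the DKO against GCN2 KO 1 (from 0) and eS31 K113R against RNF25 KO 4 (from 0). The HF response of RNF25 KO against AAVS1 called 2 (from 0) and azaC against HF in RNF25 KO 181 (from 81). More genes were tested in that setting. The stress response mean of untreated DKO against AAVS1 was −0.0566 instead of 0.124.

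Fits to only the libraries compared have fewer libraries for the estimate of spread, and called fewer genes. They called 4 with azaC in AAVS1, 26 in RNF25 KO, 68 with HF in AAVS1 (from 171), and 53, 15, 48, 24 and 65 in untreated RNF25 KO, GCN2 KO, DKO, ZNF598 KO and eS31 K113R (from 179, 116, 157, 103 and 318). Differences in azaC response from AAVS1 called 0 in GCN2 KO, 3 in the DKO and 0 in eS31 K113R. Beside these counts of 0, edgeR with all libraries called 1 and 1, with 280 and 412 genes at an unadjusted p under 0.05, and DESeq2 called 3 in GCN2 KO. azaC against HF in RNF25 KO called 2. The stress response mean of azaC in the DKO was 0.000461 instead of −0.0272.

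Replicate numbers were tried as a replicate block, although the labels do not say that they pair cultures. Libraries with the same number in different groups had a median correlation of 0.256 over 315 pairs after group means were removed, against −0.146 over 630 pairs with different numbers, and 260 of the former and 72 of the latter were over 0.1. As a hint from the data, 42 of 45 libraries had their highest mean correlation with the libraries of their own number in other groups. Pairing was accepted only if each same-number pair was over 0.1, a strict rule, and the lowest was −0.378. The numbers were therefore not taken as pairs, although most same-number pairs shared some deviation. The main fit leaves that deviation in its estimate of spread. With the replicate block azaC called 97 genes in RNF25 KO and 88 in eS31 K113R (from 57), and HF 377, 407 and 250 in AAVS1, RNF25 KO and GCN2 KO (from 171, 192 and 137). Untreated RNF25 KO, GCN2 KO, DKO and ZNF598 KO differed from AAVS1 in 273, 206, 245 and 199 genes. The GCN2 KO difference in azaC response called 3, that in HF response 86 (from 37), and azaC against HF 254 in AAVS1 (from 110) and 414 in RNF25 KO. The stress response mean of untreated GCN2 KO was 0.228 and passed (0.224 before), and that of eS31 K113R against RNF25 KO was −0.000362 instead of 0.00873.

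With limma-voom, CHAC1 stood at −0.126 instead of 1.22 after azaC in GCN2 KO and at 0.368 instead of −0.0229 in the RNF25 KO difference from AAVS1, and the DKO difference from AAVS1 called 3 genes. DESeq2 called 3 genes in the GCN2 KO difference in azaC response, 67 in that in HF response and 179 for azaC against HF in RNF25 KO.

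With GC-corrected offsets, SESN2 after azaC in GCN2 KO was −0.0319 instead of 0.0746. In differences from AAVS1, CHAC1 in RNF25 KO was 0.0181, PPP1R15A in the DKO 0.107 instead of −0.119 and TRIB3 in ZNF598 KO 0.238 instead of −0.029. The stress response mean passed in the ZNF598 KO difference (0.265, from 0.154) and in untreated ZNF598 KO (−0.140, from −0.050). azaC against HF in RNF25 KO called 50 genes, with PPP1R15A at −0.0151 instead of 0.221. Without AAVS1 untreated replicate 2 and RNF25 KO azaC replicate 2, that comparison called 21 genes, with DDIT3 at −0.0279 instead of 0.166. In the same setting the stress response mean of untreated GCN2 KO was 0.305 and passed, that of untreated ZNF598 KO was 0.0285, CHAC1 in the RNF25 KO difference was 0.00967 and TRIB3 in the ZNF598 KO difference 0.179.

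With only the eS31 K113R untreated library of that title, 1 library stood for its group and was assumed to vary like the others. azaC in eS31 K113R called 26 genes, untreated eS31 K113R 97, and the difference from AAVS1 0, where edgeR with all libraries called 1 (412 at an unadjusted p under 0.05). The stress response mean of untreated eS31 K113R was −0.0250 instead of 0.4003, although in log2 CPM that library stood 0.209 above the untreated AAVS1 mean. CHAC1 in the difference from AAVS1 was 2.48 instead of −1.48. Against RNF25 KO, CHAC1 was 2.504 instead of −1.46, PPP1R15A 0.00689 instead of −0.365, ATF3 −0.156 instead of 0.319 and DDIT3 −0.630 instead of 0.0327.

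Leaving out 1 library at a time gave 9 to 22 genes for azaC in AAVS1 (22 without untreated replicate 3), 29 to 90 in RNF25 KO (29 without azaC replicate 2, 90 and 79 without azaC replicates 1 and 3, 34 without untreated replicate 1) and 34 to 48 in eS31 K113R (34 without untreated replicate 1 or azaC replicate 2). HF gave 101 to 193 in AAVS1 (101 without HF replicate 1), 110 to 218 in RNF25 KO (110 without HF replicate 2, 119 without HF replicate 1, 123 without untreated replicate 1) and 44 to 105 in GCN2 KO (44 and 56 without HF replicates 1 and 2, 56, 68 and 68 without untreated replicates 1, 2 and 3). Against AAVS1, untreated GCN2 KO gave 74 to 142 (74 without AAVS1 replicate 2 or GCN2 KO replicate 3), the DKO 99 to 169 (99 without its replicate 2), ZNF598 KO 63 to 129 (65 and 63 without AAVS1 replicates 1 and 2, 67 without ZNF598 KO replicate 1 or 3) and eS31 K113R 209 to 333 (209 without its replicate 1).

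In the same fits the GCN2 KO difference in azaC response gave 1 to 5 genes (2 without AAVS1 untreated replicate 1, 5 without GCN2 KO azaC replicate 2), that of the DKO 2 to 5 (2 without DKO untreated replicate 2, 3 without DKO azaC replicate 1) and that of eS31 K113R 0 to 1 (0 without replicate 1 or 3 of AAVS1 or eS31 K113R untreated, AAVS1 azaC replicate 1 or 2, or eS31 K113R azaC replicate 1). For azaC against HF AAVS1 gave 51 to 116 (59, 55 and 58 without azaC replicates 1, 2 and 3, 51 without HF replicate 1 or 2) and RNF25 KO 3 to 215 (215, 17 and 137 without azaC replicates 1, 2 and 3, 36 and 3 without HF replicates 1 and 2).

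Stress response means ranged from −0.0444 to 0.340 for azaC in GCN2 KO (−0.0444 without azaC replicate 2), −0.129 to 0.233 in the DKO, 0.0915 to 0.304 in untreated GCN2 KO, −0.137 to 0.204 in the untreated DKO and −0.283 to 0.029 in untreated ZNF598 KO. In differences they ranged from 0.0731 to 0.385 for ZNF598 KO against AAVS1, −0.370 to 0.0183 for the DKO against GCN2 KO and −0.0929 to 0.134 for eS31 K113R against RNF25 KO. Single genes that did not pass crossed 0. After azaC in GCN2 KO DDIT3 ranged from −0.207 to 0.418, PPP1R15A −0.109 to 0.262, SESN2 −0.189 to 0.207 and CHAC1 −1.44 to 1.77, and in the DKO DDIT3 −0.637 to 0.376, CHAC1 −1.51 to 0.424 and TRIB3 −0.00367 to 0.331. After HF in GCN2 KO CHAC1 ranged from −0.794 to 0.0679, PPP1R15A −0.142 to 0.229 and TRIB3 −0.0496 to 0.250.

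In differences from AAVS1, CHAC1 in RNF25 KO ranged from −0.523 to 0.363, PPP1R15A in the DKO −0.662 to 0.491, in ZNF598 KO −0.0261 to 1.13 and in eS31 K113R −0.0606 to 1.09, and TRIB3 and CHAC1 in ZNF598 KO −0.484 to 0.187 and −0.0343 to 0.614. For the DKO against GCN2 KO, DDIT3 ranged from −0.725 to 0.277, SESN2 −0.0521 to 0.345, TRIB3 −0.387 to 0.0278 and CHAC1 −2.72 to 0.879, and for eS31 K113R against RNF25 KO DDIT3 −0.224 to 0.477 and ATF3 −0.0578 to 0.707. For azaC against HF in RNF25 KO DDIT3 ranged from −0.0340 to 0.317 and PPP1R15A −0.0366 to 0.663. Over all results and alternatives 6096 values kept direction and side of the threshold, 597 fell short of it, 34 newly passed, 91 moved and 91 changed sign.

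Depth limits what can be tested. The tested genes had a median of 38 counts per library, and 11078 genes were tested. RNF25 was too low to test. ASNS was too low as well, but 44.6% of its exon length is shared with a gene on the same strand, so depth was not shown to be the cause. With 3 libraries per group a simulated 2-fold difference between lines in an azaC response was recovered for 15.2% of genes in 20 simulations. Those simulations held no replicate deviation or GC slope.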

Other observations

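The comparisons here were fixed before the data were examined, and the choice to set these values side by side was made after they were seen.

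The libraries labelled RNF25 GCN2 DKO held EIF2AK4 mRNA at 39.6 ± 3.73 CPM (SD, n = 3), against 21.95 ± 2.41 CPM in GCN2 KO, and yet showed no gene past the threshold with azaC in edgeR (291 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom). An edit can end the function of a protein and leave its mRNA, so this level says nothing about the protein. In the untreated state these libraries and RNF25 KO both had TCEAL9 (442 and 381 counts over 3 libraries) and PSMB8 (210 and 168), which AAVS1 listed at 0, although PSMB8 was also found in GCN2 KO (33 counts), and both had lower genes in the first 10 Mb of chromosome 4 (−0.89 and −0.96).

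DAZL was the only methylation-silenced germline gene that could be tested after 4 h of azaC, and it did not change in RNF25 KO (0.06, adjusted p = 0.987).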
